A study of Mus musculus with 3 samples.

How the data were processed

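The series measured the transcriptomes of single mouse embryonic stem cells. These are pluripotent cells derived from the blastocyst. The cells carried loxP-flanked alleles of Mll1 (the gene now named Kmt2a, which encodes a histone H3 lysine 4 methyltransferase) and a tamoxifen-inducible Cre recombinase on a C57BL/6J background. Each of 3 chips, called plates here, held 3 cell types: control cells, cells lacking Mll1 (deleted), and cells in which MLL1 was inhibited (inhibited). The plate numbers are 105102, 105106 and 105107, and they are called plates 1, 2 and 3. The labels do not name the inhibitor, its dose or the time of treatment, and do not say which exons were deleted. Nothing says that the plates came from separate cultures, so p-values here measure the spread between plates, which may be technical.

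Per the labels' protocols, RNA of selected cells was reverse transcribed on the chip with SMARTScribe reagents and a barcoded oligonucleotide, amplified with SeqAmp, and made into libraries with a modified Nextera XT kit. Per the submitters' processing notes, STAR 2.5.2b, featureCounts and Subread 1.4.6-p1 were used with the mouse build mm10, in an order the notes do not give. The deposited count tables hold raw counts of unique molecular identifiers (UMIs) per gene and well, not normalised by the authors. In all 4640 wells the row sum and the number of detected genes equalled those in the deposited report of each plate. That report also gives each well's type, and the types of wells were taken from it and never from expression. How reads that fit several genes were counted, whether strand was used and which transcript end was counted is not given in the sources used here. Genes with near-identical copies or processed pseudogenes (Zscan4 and Usp17l families, keratins, actins, ribosomal protein genes, mitochondrial genes with nuclear copies) are therefore uncertain.

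Gene identifiers were matched to the GENCODE M21 annotation of GRCm38 (mm10), which names 28641 of the 29267 identifiers; 626 had no match. Coordinates are from that annotation, counted from 1. Spike-in and reporter sequences, which name no mouse gene, took 0.742, 0.648 and 0.615% of UMIs on plates 1, 2 and 3 and were left out of library sizes and tests. Of 4610 wells of the 3 cell types, those with at least 1000 detected genes and under 20% of UMIs from the mitochondrial genome were kept. This left 4413 wells, and 197 were left out, 86 of them for the mitochondrial share. There were also 15 wells of control RNA and 15 without cells, used only as background. No doublet caller was run; a fit without the deepest 5% of wells of each plate and cell type was added after the data had been seen.

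Counts were summed over the kept wells of each plate and cell type, which gave 9 libraries; cells were not treated as replicates. They were tested with edgeR 4.0.16 (R 4.3.3), with TMM normalisation, filterByExpr and the quasi-likelihood F test. One model held the cell type and the plate as a block, with Benjamini-Hochberg (BH) adjustment and a threshold of 0.05. The block was chosen because the labels put all 3 cell types on every plate. Deviations from the cell type means correlated at 0.0782 to 0.141 over the 9 pairs of libraries from the same plate and at -0.101 to 0.00858 over the 18 pairs from different plates. CPM values are counts scaled by the TMM-normalised library size. Levels are means and SD over 3 plates; fold changes are log2 values with the standard error (SE) of the fit.

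Before the data were examined, 30 gene lists were fixed on cell identity, chromatin, cell cycle, stress and metabolism. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the 30 lists. The genes named were also fixed by rule beforehand: Kmt2a and Gc in each comparison, and up to 4 members per list with the smallest p. To these the rule added the 10 largest rises and falls against control, and the 5 largest between inhibition and deletion. These had to pass the threshold with the same sign on every plate and a mean of at least 10 CPM. Genes named outside this rule are marked as chosen after their values were seen.

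The share of wells with a Zscan4 family UMI was computed after thinning each kept well to 5869 UMIs, the 10th percentile of totals; 3971 wells reached that depth and 442 did not. Differences within plates were tested by an exact two-sided permutation of their signs, whose smallest p over 3 plates is 0.25. Confidence intervals are 95% exact (Clopper-Pearson) binomial intervals and cover counting error only.

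The test was tried on simulated counts with 200 changed genes per comparison, all drawn from genes with a mean of at least 10 CPM. Of genes changed 1.5-fold it recovered 44% for deletion (16658 genes tested), 44% for inhibition (16689 genes) and 37% for inhibition against deletion (16672 genes); of genes changed 2-fold it recovered 85, 83 and 82%. Of its calls there, 13 of 142, 7 of 134 and 7 of 126 were false. Recovery was not measured for genes below 10 CPM or with fewer changed genes. Alternatives were a fit without the block, RLE size factors, DESeq2 1.42.0, no filter on low counts, no filter on wells, at least 2000 genes per well, wells thinned to 5869 UMIs before summing (the 442 shallower wells, 101 of them deleted cells of plate 3, were left out, and 10864 genes were tested against 17119), and leaving out each plate. Cell-level summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.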

Results

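Single embryonic stem cells of 3 types were compared on 3 plates: control, Mll1 deleted and Mll1 inhibited. After filtering, 1513 control, 1310 deleted and 1590 inhibited cells remained, with a median of 39644, 34721 and 32890 UMIs per cell. Over all kept wells the median was 36355 UMIs and 3933 genes, and single wells held 1611 to 1108770 UMIs. Summed per plate and cell type, the 9 libraries held 25914860 to 43773924 UMIs, and the deepest 5% of wells held 20 to 34% of them. Wells without cells held a median of 165 UMIs (range 43 to 438, n = 15). The median share of mitochondrial UMIs differed between cell types on every plate. It was 3.11, 3.06 and 3.18% in control cells on plates 1 to 3, 4.16, 3.81 and 3.87% in deleted cells, and 3.48, 3.24 and 3.42% in inhibited cells.

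Kmt2a (ENSMUSG00000002028, the Mll1 gene; GRCm38/mm10 chromosome 9, 44803355 to 44881296, minus strand) was measured in every library. Its level was 50.2, 50.2 and 54.7 CPM in control cells on plates 1 to 3, 62.1, 49.9 and 39.2 CPM in deleted cells, and 40.6, 43.4 and 46.7 CPM in inhibited cells. Inhibited cells were thus below control cells on every plate. Neither deletion (log2 difference -0.05 ± 0.16 SE, adjusted p = 0.959) nor inhibition (-0.25 ± 0.16, adjusted p = 0.708) differed from control beyond the spread between plates. Because the labels name neither the deleted exons nor the transcript end counted, these counts do not check the genotype. The other members of the MLL and COMPASS complexes, which methylate histone H3 lysine 4, did not shift as a list after deletion (19 measured, camera adjusted p = 0.926) or inhibition (adjusted p = 0.937). Dpy30, a core subunit of these complexes, was the 1 member past the threshold when adjusted over the list alone (-0.27 ± 0.07 after deletion, adjusted p = 0.0436). Over all genes it did not pass (adjusted p = 0.222). The list of Hox genes and other MLL1 targets, developmental regulators mostly at a few CPM or less here, was not called either (29 measured; adjusted p = 0.979 after deletion and 0.861 after inhibition).

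The first comparison asked which transcripts differ when Mll1 is deleted. The 2 mitochondrial ribosomal RNAs rose. The large subunit RNA mt-Rnr2 (mitochondrial genome, 1094 to 2675) went from 5513 ± 687 CPM in control to 8918 ± 1373 CPM in deleted cells (SD, n = 3), a log2 difference of 0.69 ± 0.04 (SE). The small subunit RNA mt-Rnr1 (mitochondrial genome, 70 to 1024) rose by 0.46 ± 0.06. Anxa2 (chromosome 9, 69453620 to 69491795), which encodes a calcium-dependent phospholipid-binding protein, rose by 0.78 ± 0.07, from 142 ± 15.5 to 245 ± 42.0 CPM (SD, n = 3). Lgals3 (chromosome 14, 47367751 to 47386160), which encodes the lectin galectin-3, rose by 0.68 ± 0.07. Dusp9 (chromosome X, 73639419 to 73643514), a phosphatase of MAP kinases, rose by 0.64 ± 0.08. Sqstm1 (chromosome 11, 50199366 to 50210827), the autophagy receptor p62, rose by 0.56 ± 0.06. Each was higher in deleted than in control cells on all 3 plates. These were the 6 genes past the threshold among 17119 tested, with none lower. Their adjusted p in edgeR's quasi-likelihood test with BH adjustment was 0.000103 for mt-Rnr2, 0.00665 for Anxa2, 0.0141 for Lgals3, 0.0225 for Sqstm1, 0.0432 for Dusp9 and 0.0433 for mt-Rnr1. At an unadjusted p under 0.05, 875 genes were higher and 893 lower, against about 856 in all by chance. Of the 6, mt-Rnr2 alone passed in each fit that left out a plate (5, 1 and 3 genes were called without plates 1, 2 and 3), and without the plate as a block 0 genes passed edgeR's test (1035 at an unadjusted p under 0.05). The count was 77 (32 up, 45 down) of 10864 genes tested with wells thinned to equal depth, which leaves out shallower wells and where Anxa2 did not pass (adjusted p = 0.257; Lgals3 did not pass without the deepest 5% of wells, 0.0968), 179 (110 up, 69 down) with no filter on low counts and 334 (175 up, 159 down) with DESeq2.

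**Figure D1:**
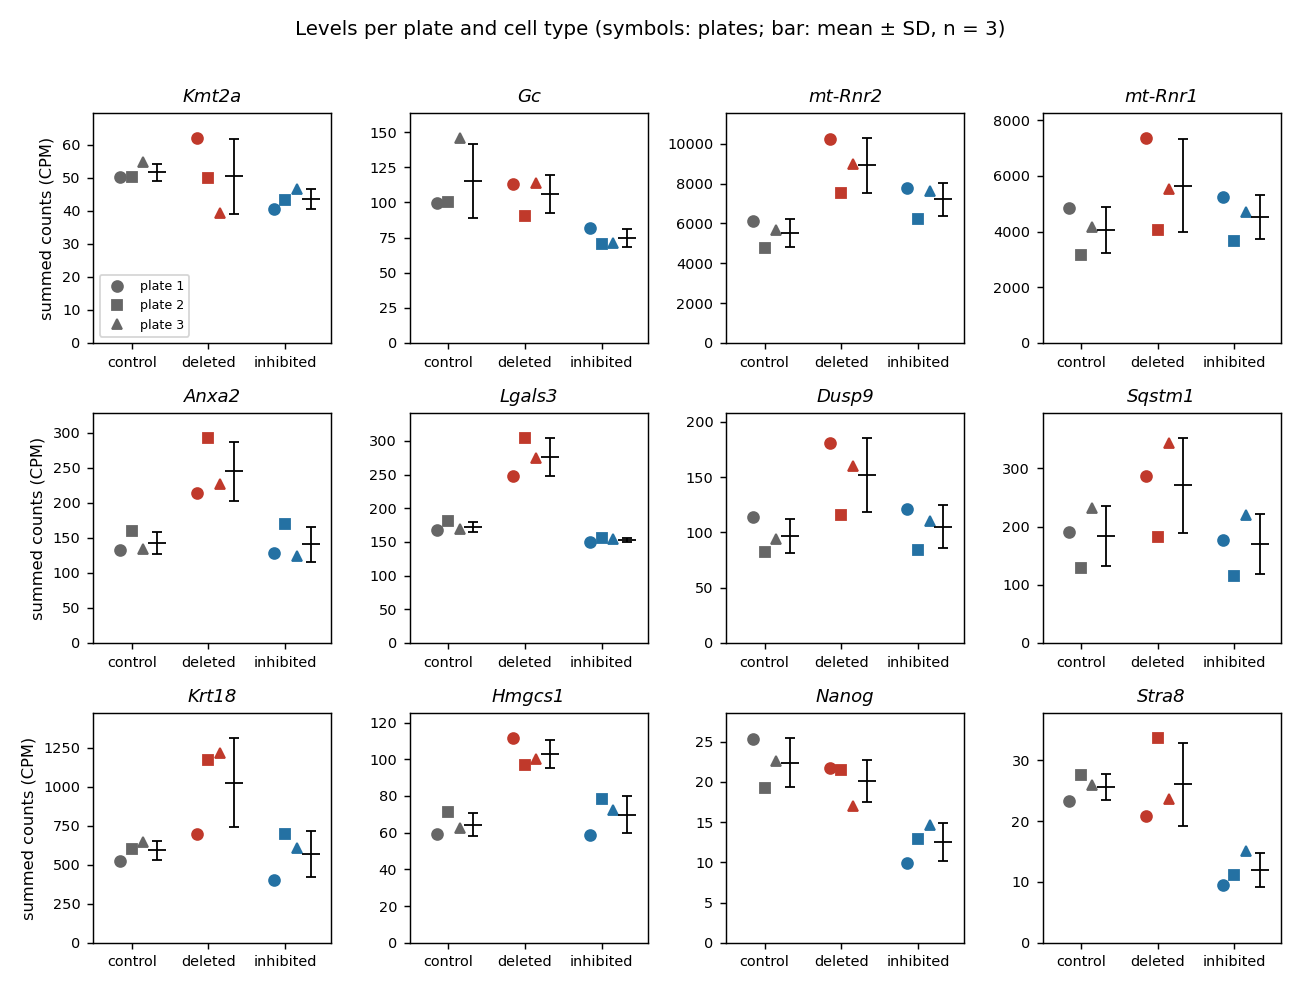
Levels of 12 genes in CPM (vertical axis, from 0) in control, deleted and inhibited cells; symbols are the 3 plates and the black bar is the mean ± SD over plates. The mt-Rnr2 level on each plate was highest in deleted cells, at 7510 to 10254 CPM. Kmt2a in deleted cells (39.2 to 62.1 CPM) spanned the other cell types, and in inhibited cells it was below control on every plate.

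Gc, the vitamin D binding protein of serum (chromosome 5, 89417522 to 89457898), was at 106 ± 13.4 CPM in deleted and 115 ± 26.5 CPM in control cells (SD, n = 3; log2 difference -0.11 ± 0.13 SE, edgeR adjusted p = 0.838). The vitamin D pathway list was not called after deletion (8 measured, camera adjusted p = 0.632).

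Among the lists, genes of cholesterol synthesis shifted upward after deletion, with 21 of 22 members above 0 and a median log2 difference of 0.42. Hmgcs1, which encodes the cytosolic HMG-CoA synthase, stood at 0.68 ± 0.12, the demethylase gene Cyp51 at 0.59 ± 0.12, the methyl sterol oxidase gene Msmo1 at 0.54 ± 0.09 and the farnesyl diphosphate synthase gene Fdps at 0.53 ± 0.11. No member passed over all genes, and 6 rose when adjusted over the list alone, these 4 among them. With wells thinned to equal depth Hmgcs1 passed over all genes (edgeR adjusted p = 0.0130). Trophectoderm markers, genes of the outer layer of the blastocyst, also shifted upward, with 18 of 20 members above 0 and a median of 0.57. The keratin genes Krt18 (0.75 ± 0.11), Krt8 (0.64 ± 0.13) and Krt19 (0.61 ± 0.16) and the signalling gene Wnt7b (0.92 ± 0.28) rose when adjusted over the list alone (4 members), and 0 passed over all genes. Of 12 measured transcripts of the mitochondrial genome, 11 were above 0 (median 0.22); 2 rose over all genes and 8 when adjusted over the list alone, among them mt-Nd4 (0.39 ± 0.06) and mt-Co1 (0.26 ± 0.05), which encode subunits of complexes I and IV. With wells thinned to equal depth the messenger RNAs mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5, mt-Nd6 and mt-Co1 also rose past the threshold over all genes. Their edgeR adjusted p ran from 1.6e-06 (mt-Nd4) to 0.0305 (mt-Nd1). The median mitochondrial share of UMIs was also higher in deleted cells, as given above. Camera's adjusted p at the preset correlation was 1.02e-06 for cholesterol synthesis and 2.61e-05 for each of the other 2 lists. With an estimated correlation these calls were lost, at adjusted p = 0.366 for cholesterol synthesis and trophectoderm and 0.591 for the mitochondrial genome. With fry, which asks only whether members move one way, each of the 3 had an adjusted p of 0.0878. Cholesterol synthesis and trophectoderm kept their calls at the preset correlation in every fit that left out a plate; the mitochondrial genome lost it without plate 1 (adjusted p = 0.0584).

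Another 5 lists passed after deletion at the preset correlation, and each lost its call with an estimated one. The estimate was below the preset 0.01 for p53 targets (0.0096), the immediate early and stress response list (0.0085) and blood markers (-0.048). A higher correlation between members therefore does not account for those losses. The extracellular matrix and adhesion list was higher (17 of 23 members above 0, median 0.19, adjusted p = 0.00934, or 0.366 with an estimated correlation), with 3 members up and 1 down when adjusted over the list alone and 0 over all genes. It shares Krt8 and Krt18 with the trophectoderm list; its others were the tetraspanin gene Cd9 (0.32 ± 0.07) and the secreted phosphoprotein gene Spp1 (-0.28 ± 0.08). The immediate early and stress response list was higher (13 of 20, median 0.13, adjusted p = 0.0336, or 0.366 when estimated), with 4 members up when adjusted over the list alone: the transcription factor genes Fos (0.68 ± 0.15) and Fosb (0.94 ± 0.30), the heat shock gene Dnajb1 (0.41 ± 0.09) and the phosphatase gene Dusp1 (0.33 ± 0.09). The p53 target list was higher (16 of 21, median 0.13, adjusted p = 0.0336, or 0.366); the death receptor gene Tnfrsf10b (0.66 ± 0.13) and the membrane protein gene Perp (0.28 ± 0.08) rose and Rps27l (-0.17 ± 0.05) fell when adjusted over the list alone. Nuclear genes of oxidative phosphorylation were slightly lower (28 of 31 below 0, median -0.08, adjusted p = 0.0336, or 0.854), with no member past either adjustment; Cox8a and Uqcrb, subunits of complexes IV and III, were each at -0.20. Blood and endothelial markers were higher (5 measured, 4 above 0, median 0.55, adjusted p = 0.0425, or 0.366), with the adhesion gene Pecam1 at 0.75 ± 0.28 and no member past either adjustment. Each of the 5 lost its call when at least 1 plate was left out. Oxidative phosphorylation (adjusted p 0.0818 to 0.493), the stress list (0.0958 to 0.211) and p53 targets (0.0818 to 0.218) lost it without any one of the plates. Extracellular matrix lost it without plates 2 and 3 (0.170 and 0.130), and blood markers without plate 1 (0.484). With wells thinned to equal depth all but oxidative phosphorylation lost it (0.0556 to 0.978).

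The remaining 22 lists were not called after deletion (camera adjusted p from 0.105 to 0.995). Pluripotency factors were centred near 0 (28 measured, median -0.04, adjusted p = 0.658). Among them the growth factor and co-receptor genes Tdgf1 (-0.30 ± 0.07), Gdf3 (-0.39 ± 0.10) and Fgf4 (-0.71 ± 0.20) fell when adjusted over the list alone, and 0 over all genes. With wells thinned to equal depth Fgf4 passed over all genes (edgeR adjusted p = 0.0284). Among imprinted genes (21 measured, adjusted p = 0.658), the retrotransposon-derived gene Peg10 (0.41 ± 0.07) and the growth factor gene Igf2 (0.60 ± 0.13) rose and the noncoding RNA Meg3 (3.92 CPM in control against 0.319 CPM in deleted cells) fell when adjusted over the list alone. Ldha, which encodes lactate dehydrogenase, was the 1 member of the glycolysis and hypoxia list to pass that adjustment (-0.23 ± 0.05; list adjusted p = 0.922). The smooth muscle actin gene Acta2 was the 1 fibroblast and feeder marker to pass it (1.73 ± 0.44; list adjusted p = 0.342). No called list had a median, mean and test of different sign in this comparison; among the lists not called, 7 did.

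The second comparison asked which transcripts differ when MLL1 is inhibited. The mitochondrial large subunit RNA mt-Rnr2 rose by 0.39 ± 0.04 (SE), from 5513 ± 687 to 7201 ± 848 CPM (SD, n = 3), and was higher on all 3 plates. Lower levels that missed the threshold over all genes included Nanog, a transcription factor gene of naive pluripotency (22.4 ± 3.09 CPM in control, 12.5 ± 2.40 CPM in inhibited cells, SD, n = 3; log2 difference -0.84 ± 0.21, edgeR adjusted p = 0.355). They also included Gc (-0.61 ± 0.13, adjusted p = 0.294), Dnmt3l, a cofactor of de novo DNA methylation (-0.49 ± 0.10, adjusted p = 0.277), and Stra8, a gene of meiotic entry (-1.11 ± 0.19, adjusted p = 0.223). In edgeR's quasi-likelihood test with BH adjustment mt-Rnr2 was the 1 gene past the threshold (adjusted p = 0.0279); at an unadjusted p under 0.05, 816 genes were higher and 724 lower, against about 856 in all by chance. Leaving out plate 1, 2 or 3 ended that call (adjusted p 0.181 to 0.783), with 0 genes past the test each time (1104, 1092 and 1352 at an unadjusted p under 0.05), and without the block 0 genes passed (851 unadjusted). The count was 90 (31 up, 59 down) of 10864 genes tested with wells thinned, 108 (49 up, 59 down) with no filter on low counts and 277 (177 up, 100 down) with DESeq2.

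Genes of the germline and meiosis shifted downward after inhibition, with 17 of 22 measured members below 0 and a median log2 difference of -0.39. When adjusted over the list alone, 4 fell: Stra8, the RNA-binding protein gene Dazl (-2.28 ± 0.40), the synaptonemal complex gene Sycp1 (-0.71 ± 0.15) and the piRNA pathway gene Mael (-0.79 ± 0.23). Over all genes 0 passed. With wells thinned to equal depth, Sycp1 alone of these 4 passed over all genes (edgeR adjusted p = 0.0224). Camera gave the list an adjusted p of 0.0016 at the preset correlation, which stayed past the threshold in every fit that left out a plate. With an estimated correlation its adjusted p was 0.179, although that estimate (-0.032) was below the preset, and with fry 0.0109. The S phase list shifted upward (17 of 22 above 0, median 0.16, adjusted p = 0.00243, or 0.179 with an estimated correlation), with the helicase subunit gene Gins2 at 0.41 ± 0.10, the ribonucleotide reductase gene Rrm2 at 0.23 ± 0.07 and the cyclin gene Ccne2 at 0.31 ± 0.11. No member passed either adjustment. Its adjusted p was 0.0274 with fry, and 0.0802 at the preset correlation without plate 1. Its estimated correlation (-0.0037) was also below the preset.

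The immediate early and stress response list was higher after inhibition too (16 of 20 above 0, median 0.26, camera adjusted p = 0.00195, or 0.179 with an estimated correlation). Dusp1 (0.56 ± 0.09), Dnajb1 (0.36 ± 0.09) and the early response gene Ier2 (0.29 ± 0.09) rose when adjusted over the list alone, and 0 over all genes. The p53 target list was higher (20 of 21, median 0.12, adjusted p = 0.00473, or 0.199), with Phlda3, an inhibitor of AKT signalling, at 0.46 ± 0.15 and no member past either adjustment. Blood and endothelial markers were lower (5 measured, 3 below 0, median -0.87, adjusted p = 0.0442, or 0.314), with Pecam1 at -0.87 ± 0.29 and no member past either adjustment. The stress list lost its call without plate 3 (adjusted p = 0.0870), the p53 list without plates 1 and 3 (0.170 and 0.0611) and the blood list without any one of the plates (0.0802 to 0.934). The p53 and blood lists also lost it with wells thinned (0.224 and 0.347).

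The other 25 lists were not called after inhibition (camera adjusted p from 0.171 to 0.937). Pluripotency factors had a median of -0.04 (28 measured, adjusted p = 0.300); Dppa5a, an RNA-binding protein gene of pluripotent cells (-0.38 ± 0.09), and Nanog fell when adjusted over the list alone, and 0 over all genes. With wells thinned to equal depth this list was called lower (adjusted p = 0.00862), as was extracellular matrix and adhesion (0.00465). Gc fell when adjusted over the vitamin D pathway list alone (list adjusted p = 0.359), and Dnmt3l over the DNA methylation list alone (list adjusted p = 0.937). The amino acid transporter subunit gene Slc3a2 (0.43 ± 0.08) rose and the stress gene Nupr1 (-0.38 ± 0.09) fell when adjusted over the unfolded protein and amino acid stress list alone (list adjusted p = 0.372). Meg3 was at 0.301 CPM in inhibited cells and fell when adjusted over the imprinted list alone (list adjusted p = 0.405). Cholesterol synthesis (15 of 22 above 0, median 0.09, adjusted p = 0.300) and trophectoderm (12 of 20 above 0, median 0.12, adjusted p = 0.405) were not called. No called list had a median, mean and test of different sign in this comparison; among the lists not called, 4 did.

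**Figure D2:**
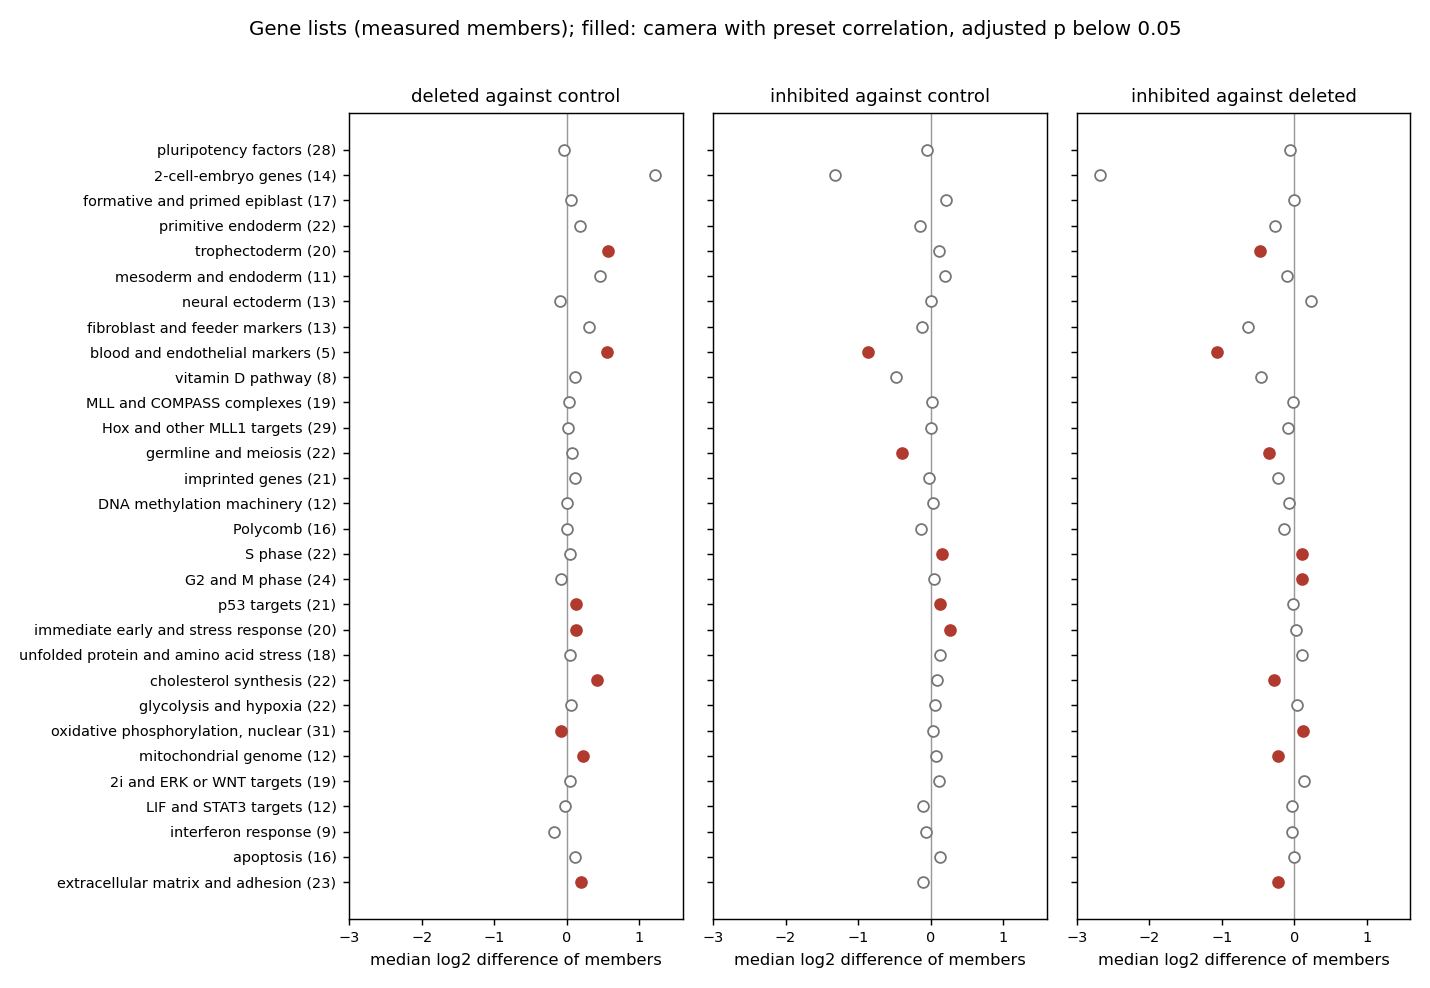
Median log2 difference over the measured members of each of 30 gene lists (horizontal axis; number of measured members in brackets) for the 3 comparisons; filled points passed camera at the preset correlation of 0.01, and none passed with an estimated correlation. Cholesterol synthesis lay at 0.42 after deletion and 0.09 after inhibition; medians of the 2-cell-embryo list rest on genes counted in few wells.

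The third comparison set inhibited against deleted cells directly. Among genes past the threshold with a mean of at least 10 CPM, those that fell most from deleted to inhibited cells were Acta1, the skeletal muscle actin gene (-2.09 ± 0.24 SE; 31.1 ± 7.27 against 7.21 ± 0.985 CPM, SD, n = 3), and Nkain4, a sodium pump interacting protein gene (-1.76 ± 0.22). Next in that group came Morc1, a gene of transposon silencing in the germline (-1.45 ± 0.25), Serpinb9b, a protease inhibitor gene of a cluster of close paralogs (-1.38 ± 0.21), and the annexin gene Anxa1 (-1.36 ± 0.18). Those that rose most were Ramp3, which encodes a receptor activity-modifying protein (1.05 ± 0.15), the nuclear phosphoprotein gene Anp32a (0.85 ± 0.12), Gins2 (0.70 ± 0.11), the RNA exosome gene Exosc8 (0.58 ± 0.08) and the ribosome-binding factor gene Rbfa (0.52 ± 0.09). The keratin genes Krt19 (-1.12 ± 0.16), Krt8 (-0.89 ± 0.14) and Krt18 (-0.85 ± 0.11) and Igf2 (-0.74 ± 0.13) were lower in inhibited cells, and Ldha was higher (0.32 ± 0.05). Of the 6 genes that rose after deletion, 5 were lower in inhibited than in deleted cells: Lgals3 (-0.84 ± 0.07), Anxa2 (-0.80 ± 0.07), Sqstm1 (-0.67 ± 0.06), Dusp9 (-0.52 ± 0.08) and mt-Rnr2 (-0.30 ± 0.04). The deleted libraries enter both comparisons, so these are not independent of the first result. The difference for mt-Rnr1 (-0.29 ± 0.06) had an adjusted p of 0.0852, and Kmt2a (-0.20 ± 0.16, adjusted p = 0.649) and Gc (-0.49 ± 0.13, adjusted p = 0.142) also did not pass. With wells thinned to equal depth mt-Rnr1 (-0.35, edgeR adjusted p = 5.91e-05) and Gc (-0.49, 0.0306) passed, and Kmt2a did not.

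In edgeR's quasi-likelihood test with BH adjustment 16 genes rose and 37 fell between deleted and inhibited cells, 53 in all, with an adjusted p of 0.0111 for Acta1, 0.0185 for Krt18, 0.0269 for Ramp3 and 0.0497 for Igf2. At an unadjusted p under 0.05, 1195 were higher and 1143 lower. The count was 5 without plate 1 and 0 without plate 2 (1630 at an unadjusted p under 0.05), and 73 without plate 3, where 54 rose and 19 fell; 4, 0 and 23 of the 53 passed there. It was 3 without the block, 158 (71 up, 87 down) of 10864 genes tested with wells thinned, 383 (176 up, 207 down) with no filter on low counts, 734 (390 up, 344 down) with DESeq2, and 31 without the deepest 5% of wells. Of the 53, 38 passed with wells thinned and 18 without the deepest wells. Among the genes named above, Serpinb9b (adjusted p = 0.509), Rbfa (0.108), Igf2 (0.0880), Krt19 (0.0726), Morc1 (0.0705) and Ldha (0.0634) lost their calls with wells thinned. Without the deepest wells these 6 (0.0777 to 0.210), Ramp3 and Nkain4 (0.0531 each), Krt18 (0.0661) and Gins2 (0.0825) lost theirs.

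Between inhibited and deleted cells 9 lists passed at the preset correlation and none with an estimated one. For germline, S phase and blood markers that estimate (-0.032, -0.0037 and -0.048) was below the preset. The extracellular matrix and adhesion list was lower (20 of 23 below 0, median -0.22, camera adjusted p = 0.000301, or 0.224 with an estimated correlation), with 2 members down over all genes (Krt8 and Krt18) and 8 when adjusted over the list alone, among them the integrin gene Itga6 (-0.56 ± 0.14) and the matricellular gene Sparc (-0.26 ± 0.07). Trophectoderm markers were lower (15 of 20 below 0, median -0.48, adjusted p = 0.00731, or 0.299), with 3 down over all genes (the 3 keratin genes above) and 4 when adjusted over the list alone, the last being Krt7 (-0.92 ± 0.23). Germline and meiosis genes were lower (17 of 22 below 0, median -0.35, adjusted p = 0.00121, or 0.224), with 5 down when adjusted over the list alone and 0 over all genes; Stra8 was at -1.11 ± 0.19 and the homeobox gene Rhox6 at -1.01 ± 0.25. Cholesterol synthesis was lower (20 of 22 below 0, median -0.28, adjusted p = 0.000594, or 0.370), with 3 down when adjusted over the list alone, Hmgcs1 (-0.57 ± 0.12) first, and 0 over all genes. The mitochondrial genome was lower (12 of 12 below 0, median -0.23, adjusted p = 0.00147, or 0.569), with 1 down over all genes and 6 when adjusted over the list alone. Blood and endothelial markers were lower (5 of 5 below 0, median -1.07, adjusted p = 0.00147, or 0.224), with Pecam1 (-1.61 ± 0.29) down when adjusted over the list alone and 0 over all genes.

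Nuclear oxidative phosphorylation genes were higher in inhibited than in deleted cells (26 of 31 above 0, median 0.12, camera adjusted p = 0.00188, or 0.563 with an estimated correlation), with the subunit genes Atp5g1 (0.26 ± 0.06) and Ndufa13 (0.25 ± 0.06) up when adjusted over the list alone and 0 over all genes. S phase genes were higher (19 of 22, median 0.10, adjusted p = 0.00731, or 0.224), with Gins2 up over all genes and 5 members up when adjusted over the list alone. G2 and M phase genes were higher (22 of 24, median 0.10, adjusted p = 0.0436, or 0.563), with the survivin gene Birc5 (0.24 ± 0.06) up when adjusted over the list alone and 0 over all genes. Fry called 5 of the 9 (adjusted p of 0.00913 for germline, 0.0125 for blood markers, 0.0133 for S phase, 0.0272 for extracellular matrix and 0.0486 for trophectoderm). Extracellular matrix and germline kept the preset call in every fit that left out a plate; the other 7 lost it without plate 1 (adjusted p 0.0518 to 0.331). Oxidative phosphorylation and S phase also lost it without plate 2 (0.149 and 0.0511), trophectoderm without plate 3 (0.0999), and G2 and M phase without either (0.0511 and 0.189). With wells thinned it was lost by cholesterol synthesis and G2 and M phase (0.0505 each) and blood markers (0.272). The other 21 lists were not called (camera adjusted p from 0.0535 to 0.945). No called list had a median, mean and test of different sign in this comparison; among the lists not called, 5 did.

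Whether deletion and inhibition changed the same genes was then examined. The calls of the 2 comparisons against control shared 1 gene, mt-Rnr2, against a mean of 0.075 when unchanged groups were simulated against the same controls 40 times. At an unadjusted p under 0.05, 153 genes were higher in both, against a mean of 94.9 (highest 116) by that simulation and 41.7 for independent lists, and 192 were lower in both, against 59.3 (highest 78) and 37.8. Another 51 went in opposite directions, against 0.825 by simulation. The control wells of each plate were also split at random, so that each comparison had its own control wells. The counts were then 71 and 69 higher in both, 146 and 121 lower in both, and 64 and 140 opposite. Both sets of wells came from the same control cells of the plate. A deviation of those cells on a plate therefore stayed shared. Over 7577 genes the fold changes had a covariance of 0.0150, against 0.0169 from the shared controls alone, a difference of -0.0019; with split controls it was 0.00618 and 0.000414. The correlation across genes, which are not independent replicates, was 0.304 against 0.501 by simulation. With wells thinned to equal depth the calls shared 16 genes, 6 higher in both and 10 lower in both with 0 opposite, against 0.0913 and 0.244 for independent lists. The counts in both thus lay above the simulation and the covariance did not. The simulation leaves out the effects and independent lists leave out the shared controls, so whether the treatments share changes beyond mt-Rnr2 was left open.

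Genes of the 2-cell embryo, expressed in rare cells of embryonic stem cell cultures, were examined by the share of wells with a UMI of the Zscan4 family (5 near-identical genes, counted together). At equal depth, 2 of 579, 5 of 519 and 2 of 312 control wells had such a UMI on plates 1 to 3 (0.345, 0.963 and 0.641%), a mean of 0.650 ± 0.309% (SD, n = 3). In deleted cells it was 1 of 374, 4 of 332 and 3 of 441 wells (mean 0.717 ± 0.470%), and in inhibited cells 1 of 490, 1 of 502 and 1 of 422 (mean 0.213 ± 0.0205%). The widest 95% exact binomial interval of a single library at that depth ran from 0.329 to 3.06% (deleted cells, plate 2). Deletion differed from control by 0.0675 ± 0.162 percentage points (SD of the within-plate differences), higher on 2 of 3 plates (exact permutation of signs, p = 0.75). The sign of that difference turned after thinning to the 25th percentile of totals (-0.156 points, 1 plate higher). It also turned with at least 2000 genes per well (-0.105 points, 0 plates higher). With all UMIs the mean turned as well (-0.249 points), though 2 plates were higher. Inhibition differed by -0.437 ± 0.313 percentage points, lower on all 3 plates (exact permutation of signs, p = 0.25, the smallest that 3 plates allow). Counting only wells with at least 2 such UMIs it differed by -0.246 ± 0.454 points (p = 1 by the same permutation), and after thinning to the 25th percentile of totals by -0.547 ± 1.09 points (p = 0.5), each with 1 plate higher. With all UMIs of each well, at unequal depth, the shares were 2.56% in control, 2.31% in deleted and 1.19% in inhibited cells. The wells without cells hold too few UMIs to give a background share. With all UMIs, 65 of the 86 wells with such a UMI had exactly 1. On plate 3, where 1 deleted well held 2359, these were 11 of 11 inhibited and 8 of 9 control wells, so exchange of barcodes is not excluded as a source of part of these shares. The 2-cell-embryo list was not called in any of the 3 comparisons (14 of 34 members measured; camera adjusted p = 0.658, 0.322 and 0.158), though without plate 2 it was called higher after deletion (adjusted p = 0.00909). Of its members the deubiquitinase gene Usp17lb was lower in inhibited cells (0.0206 CPM) than in deleted cells (2.70 CPM; adjusted p = 0.0437), and it belongs to a family of close copies counted in few wells.

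**Figure D3:**
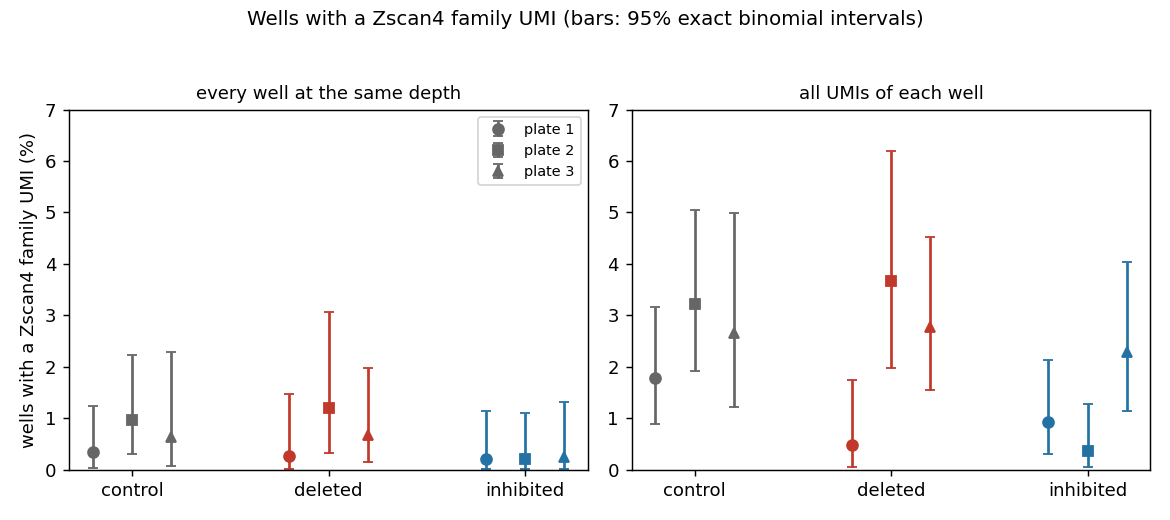
Percentage of wells with at least 1 UMI of the Zscan4 family (vertical axis) in control, deleted and inhibited cells, with every well at the same depth (left) and with all UMIs (right); symbols are the 3 plates and bars are 95% exact binomial intervals. At equal depth the intervals of the cell types overlap on every plate, with shares of 0.199 to 1.20%.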

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

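Of the tests here, the ratio of mitochondrial ribosomal to messenger RNA, the mt-Rnr2 difference on plate 3, the values set beside plate 3 from plates 1 and 2, the spike-in ratio and the splits of the libraries were chosen only after the result was seen.

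The rise of mitochondrial ribosomal RNA after deletion was weighed against 3 technical explanations. A source in shallow wells would remove it among deep wells. Over the deepest 33.3% of wells by UMIs the difference in mt-Rnr2 was still 0.611 (SE 0.0302 over 3 plates). Depth does not measure damage, so this does not test for damaged wells. More mitochondrial RNA of every kind would leave the ratio of mt-Rnr2 to mitochondrial messenger RNA unchanged, but that ratio rose by 0.474 on the log2 scale (SE 0.0418); the messenger RNAs themselves differed by 0.219 (SE 0.0494). On plate 3 the source wells were rotated: deleted cells took the place of inhibited cells on plates 1 and 2, and control cells that of deleted cells. An effect of the place alone would give there what inhibition against deletion gave on plates 1 and 2 (-0.460 and -0.347), while the difference was 0.653. Gm42418, a noncoding gene known to take up reads of nuclear ribosomal RNA, moved the same way, as unequal capture of ribosomal RNA would give. It stood at 0.57 ± 0.09 after deletion and 0.33 ± 0.09 after inhibition, neither past the threshold. With wells thinned to equal depth both passed (0.74, edgeR adjusted p = 2.09e-11, and 0.38, 0.000159). The neighbouring Gm26917 did not move that way (-0.40 ± 0.15 after deletion) and was not called with wells thinned. These values were looked up after the result was seen and decide nothing. An effect of the deletion and an unequal capture of ribosomal RNA between the cell suspensions remain open. So do damaged wells and any other difference in how the cell types were treated.

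The upward shift of trophectoderm markers after deletion may come from a few wells or from the place of the source wells. If a few wells held the counts, the share of wells with a count would not rise at equal depth; the median log2 ratio of shares over the 20 members was 0.197 on average (SE 0.0772), with 0.151, 0.348 and 0.0920 on plates 1 to 3. By the same rotation, place alone would give -0.296 or -0.155 on plate 3, where the median difference was 0.757, above all 100 random lists matched on level, against 0.302 and 0.270 on plates 1 and 2. The place of the source wells is argued against as the whole cause. Shares rose on each plate but least on plate 3, where the median difference was largest. A few wells holding much of the counts are therefore not excluded. Differentiated cells in the deleted culture and a shift within most cells remain open. So does chance, which these tests do not settle. The list was called neither with an estimated correlation nor with fry (adjusted p = 0.0878). Neither of those called any of the 30 lists after deletion, so that failure is not particular to this list.

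Spike-in RNAs (ERCC and SIRV sequences), which no comparison used, appeared in wells with cells: a median of 169 UMIs per kept well, with at least 1 in 4407 of 4413 wells. The number per well exceeded that of the wells without cells. If the same amount had been given to every well, wells without cells would hold a similar number, but the median of kept wells was 230 times the mean of the wells without cells (11 UMIs in 15 wells). As a share of UMIs they took 0.670% in kept wells and 0.403% (95% exact binomial interval 0.201 to 0.720%) in wells without cells. The share in kept wells thus lay within that interval. Kept wells also held far more UMIs in all, at a median of 36355 against 165. An excess beyond that difference in depth was therefore not shown. Barcode exchange or addition together with the cells are candidate explanations that were not tested, and no biological explanation was tested.

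Wells of control RNA held a median of 904 UMIs (470 to 4152, n = 15), above the 165 of wells without cells (43 to 438, n = 15).

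The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. For deletion the real split gave 6 genes and the highest other split 1; for inhibition 1 and 0; for inhibition against deletion 53 and 0. In each case 1 of the 10 splits, the real one, gave as many genes. Only some of the splits, the real one among them, parted both libraries on all 3 plates, as the pairing by plate requires. Among those the highest other counts were again 1, 0 and 0.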

How the results depend on the processing

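Of the settings here, only the fits without the deepest 5% of wells were chosen after the data were seen. For deletion, inhibition and inhibition against deletion, which called 6, 1 and 53 genes with 1 shared by the comparisons against control, the counts were 0, 0 and 3 (0 shared) without the plate as a block, 334, 277 and 734 (40 shared) with DESeq2, 179, 108 and 383 (24 shared) with no filter on low counts, and 77, 90 and 158 (16 shared) with wells thinned to the same total, where 10864 genes were tested. Deletion called 10 genes with no filter on wells, and inhibition against deletion 31 without the deepest 5% of wells. DESeq2 left the adjusted p of 6970, 11616 and 2324 genes undefined. Leaving out each plate gave 1 to 5 genes for deletion, 0 to 0 for inhibition, 0 to 73 for inhibition against deletion and 0 to 0 shared. Of 30 lists, camera called 8, 5 and 9 at the preset correlation, 0, 0 and 0 with an estimated one, while fry called 0, 2 and 5. Lists called for deletion numbered 4 with wells thinned and 5 without the deepest wells, and those for inhibition 3 without the deepest wells; leaving out each plate gave 3 to 6, 2 to 5 and 2 to 7. The Zscan4 difference in percentage points after deletion was -0.249 unthinned, -0.156 thinned to the 25th percentile and -0.105 with at least 2000 genes per well (-0.0194 to 0.140 leaving out each plate); after inhibition it was -1.37 unthinned (-0.584 to -0.273). The estimated correlation and fry ask other questions of the same data, and fits with a plate left out have fewer libraries. For the germline, S phase, p53, stress and blood lists the estimate was below the preset. A higher correlation thus does not account for their lost calls. For p53 targets after deletion the estimate (0.00962) was close to the preset, yet camera's unadjusted p went from 0.00615 to 0.0514. With an estimate, camera judges its statistic by the few residual degrees of freedom of the 9 libraries. That raises p even at an equal correlation. How much of each loss it explains was not tested. The Kmt2a difference did not pass in any of the 11 alternatives (-0.23 to 0.15 after deletion, -0.26 to -0.05 after inhibition). RLE size factors changed no count by over 1.5 times. Over single genes named, 3543 values kept their side of the threshold, 108 lost it, 167 gained it and 0 called values reversed; over lists these were 833, 58, 9 and 0. Without the block 23 gene calls and 4 list calls were lost and none gained. The median SE of log2 differences over all tested genes was 0.302 to 0.303, so changes of that size in a typical gene were not resolved. Larger ones could be missed too. Fosb, with an SE of 0.30, did not pass at 0.94 after deletion (edgeR adjusted p over all genes = 0.321).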

Other observations

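All tests in this part were chosen after the data had been seen.

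At equal depth, the share of wells with a UMI was lower in inhibited than in control wells on all 3 plates for 29.6% of 11559 tested genes seen in at least 1% of wells, and higher on all 3 for 6.43%; for deleted wells these were 22.2 and 10.1%. A lower share after inhibition was thus common over all genes. The genes given here were picked after their values had been seen, several because they were low after inhibition. Nanog was detected in 5.03 ± 1.4% of inhibited, 6.87 ± 1.11% of deleted and 10.2 ± 2.83% of control wells (SD, n = 3 plates), Dnmt3l in 25.7 ± 2.33, 37.4 ± 4.80 and 37.1 ± 5.56%, Gc in 23.5 ± 1.44, 31.6 ± 2.08 and 36.6 ± 6.69%, Krt8 in 28.3 ± 5.55, 43.5 ± 4.33 and 37.1 ± 5.22%, and Lgals3 in 31.3 ± 5.32, 41.9 ± 2.57 and 37.5 ± 2.59%. Krt8 was higher in deleted than in control wells on 3 plates and Krt18 on 2.

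Genes of cytosolic ribosomal proteins were slightly lower after both treatments. The median log2 difference over 82 genes was -0.15 after deletion (77 below 0) and -0.14 after inhibition (70 below 0), and it was below 0 on each plate, at -0.06, -0.15 and -0.22 after deletion and -0.09, -0.11 and -0.21 after inhibition. Camera's adjusted p, over the 2 lists of this part, was 2.31e-09 and 2.58e-07 at the preset correlation but 0.207 and 0.262 with an estimated correlation, and fry's was 0.0238 and 0.0365 (0.0669 after deletion with wells thinned). These small genes have many processed pseudogenes, and both comparisons share the control libraries. Targets of NRF2, the transcription factor of the antioxidant response, went both ways between deleted and inhibited cells (19 measured, 7 above and 12 below 0, median -0.23; plate medians -0.413, -0.0112 and -0.286). When adjusted over the list alone 3 rose and 9 fell, and over all genes Sqstm1 (-0.67 ± 0.06) and the reductase genes Cbr3 (-1.01), Srxn1 (-0.82) and Nqo1 (-0.65) fell. Camera's adjusted p was 0.00585 at the preset correlation and 0.0707 with an estimated one, and fry's was 0.00206. Sqstm1 was on this list because it had been seen among the genes called; without it these were 0.0257, 0.136 and 0.00488. Against control the list was called lower after inhibition (camera adjusted p = 0.0256, or 0.158 with an estimated correlation). There 3 members were up and 3 down when adjusted over the list alone. After deletion it was called higher (camera adjusted p = 0.0202, or 0.142), with 5 members up and 3 down by that adjustment. The call after deletion was lost with wells thinned (0.164) and without Sqstm1 (0.0696).

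Zscan4 family UMIs were concentrated in few wells. Of 4339 such UMIs in kept wells, 4213 (97.1%) lay in 9 wells with at least 20 each, a minimum set after the counts were seen: 4 control, 4 deleted and 1 inhibited. Of the 86 wells with a Zscan4 UMI, 65 had exactly 1. Of 22 other genes of the 2-cell-embryo list, 18 had a higher CPM over the 9 wells than over the other wells, 3 (Tdpoz1, Pramel6 and Pramel7) had no count in them and Eif1a was lower (154 against 303 CPM). Among the 18, Usp17lc was detected in 6 of the 9 wells (560 CPM over the 9 wells, 0.0876 CPM over the other wells), Usp17le in 8 (243 against 0.238 CPM), Gm4340 in 5 (1149 against 0.266 CPM) and Ubtfl1 in 3 (224 against 0.322 CPM). Pou5f1, the gene of the pluripotency factor OCT4, was at 39.6 against 54.2 CPM and Sox2 at 161 against 126 CPM. The 9 wells had a median of 77374 UMIs, against 36020 in the others.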
